A study of Drosophila melanogaster with 20 samples.

How the data were processed

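RNA of whole Drosophila melanogaster larvae, 4 days old and kept at 25 °C, was depleted of ribosomal RNA and sequenced as 75-base read pairs. There were 4 groups of 5 libraries: control larvae of the wDah background and larvae of 3 lines with changes in the gene of the mitochondrial carrier of S-adenosylmethionine (SAM), named I172G, P223L and SAMC-null. Groups and replicate numbers were taken from the labels. The labels do not say that equal replicate numbers belong together, so the numbers did not pair samples.

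Per the submitters' processing notes, the authors used Salmon 0.11.3 and DESeq2 1.26.0 with the BDGP6 build. The deposited tables, 1 per line against control, hold 14081 genes each and a signal column per library: a normalised read count per gene. The control columns hold the same values in the 3 tables, with a largest difference of 0.005 from rounding, and the deposited mean per gene equals the mean of all 20 libraries, so all libraries share 1 normalisation. The low values are not all whole reads after scaling. The step, or value of 1 read, was taken as the most frequent low value of a library. Among values up to 20 steps, 60.9 to 80.3% per library fall within 0.1 step of a multiple, where an even spread would give 20%. Most low values thus lay near whole reads, but the rest did not, so the values were not turned into counts and no count test was used. A count test on rounded values was not tried. The deposited tables also hold the authors' log2 fold change with its standard error, a score (the Wald statistic against an absolute log2 fold change of 1, and a weight per gene), and the p-value with its adjusted value. A total of 66 genes have no p-value in each of them.

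Symbols came from the deposited tables for 13787 genes, and shared or missing symbols were replaced with those of Ensembl release 115 (BDGP 6.54), in which 13853 genes were matched by identifier. Coordinates refer to that annotation.

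Each comparison was fitted with limma 3.58.1 in R 4.3.3, with an intensity trend, on log2(value + 1) of the 5 libraries of each group, without further scaling. Genes with a value of at least 10 in at least 5 of the 10 libraries were tested, p-values were two-sided and adjusted by Benjamini-Hochberg over all tested genes, and the threshold was 0.05. The 5 comparisons were each mutant line against control, P223L against SAMC-null, and I172G against P223L. A total of 45 gene lists was fixed before the data were examined, and lists with at least 3 tested members were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison. The same test with a correlation estimated for each list was run beside it. Counts of list members past the threshold are given over all genes tested and adjusted over the list alone.

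The genes named in the text followed a rule also fixed beforehand. It took the SAM carrier gene CG4743, the 10 largest increases and the 10 largest decreases against control (5 each between mutants), and up to 4 members of each list with the smallest adjusted p. The largest changes were taken among genes past the threshold with a mean of at least 50 and with every library of 1 group above every library of the other. No fold change is given where all 5 libraries of a group are listed at 0.

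The summed normalised counts ranged from 22090000 to 36610000 per library, and divided by the step they gave about 23500000 to 35000000 reads, while the labels state 3000000. The median standard error of a log2 fold change was 0.117 for I172G, 0.104 for P223L and 0.1 for SAMC-null against control. The fit was tested on simulated data with the means of the control libraries and the spread of both groups. In these, 50 genes were changed at each fold. The fit recovered 62 to 74% of genes changed 1.5-fold, 84 to 86% at 2-fold, 88 to 98% at 4-fold and 100% at 8-fold, with 2.7 to 5.5% false calls among all calls. The simulated genes were drawn independently, and far fewer changed than were called in the real comparisons. The share of false calls need not hold for the real data.

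The alternatives planned beforehand were pseudocounts of 0.5 and 4, no filter and a filter of 50, median-ratio rescaling, each library left out in turn, replicate number as a block, all 4 groups in 1 fit, the authors' adjusted p, an estimated correlation for the lists, and split controls for the shared calls. Alternatives added after seeing the data were limma's treat against an absolute log2 fold change of 1, and, for the lists, rescaling and the fit without control replicate 4. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. All 20 libraries were used.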

Results

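Gene expression was measured by RNA sequencing of whole larvae of the fruit fly, in 5 libraries each of control larvae and of the I172G, P223L and SAMC-null lines. The lines carry changes in the mitochondrial SAM carrier, which brings SAM, the methyl donor of the cell, into mitochondria. The labels call I172G a mild mutant and P223L a severe mutant, both with a single amino acid change, and SAMC-null a severe null line. The normalised counts of a library summed on average to 34020000 ± 910000 (SD, n = 5) in control, 34730000 ± 1460000 in I172G, 25560000 ± 510000 in P223L and 22370000 ± 290000 in SAMC-null. The 10 most abundant genes held 22.8 ± 1.3% of these counts in control and 15.6 ± 1.1% in SAMC-null (SD, n = 5). A value of 10 or more was reached by 12252 ± 102 genes in control, 12037 ± 131 in I172G, 11105 ± 59 in P223L and 11177 ± 31 in SAMC-null. The labels do not say whether the libraries of a group came from separate cultures, so every p-value measures only the spread between these libraries. Each line was compared with the same control, so an effect of the carrier cannot be told apart from other differences between the strains.

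Across 12639 genes, the first principal component held 83.5% of the variance and set P223L and SAMC-null, at -118 to -109.33, apart from control and I172G, at 94.91 to 132.47. On the second component, with 4.6% of the variance, control replicate 4 lay at 5.26, while the other controls lay between -49.71 and -32.67 and the I172G libraries between 23.99 and 45.37. Pearson's r across genes, which are not independent replicates, was 0.976 to 0.98 between P223L and SAMC-null libraries and 0.758 to 0.82 between P223L and control libraries. Among control libraries it was 0.96 to 0.985.

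**Figure D1:**
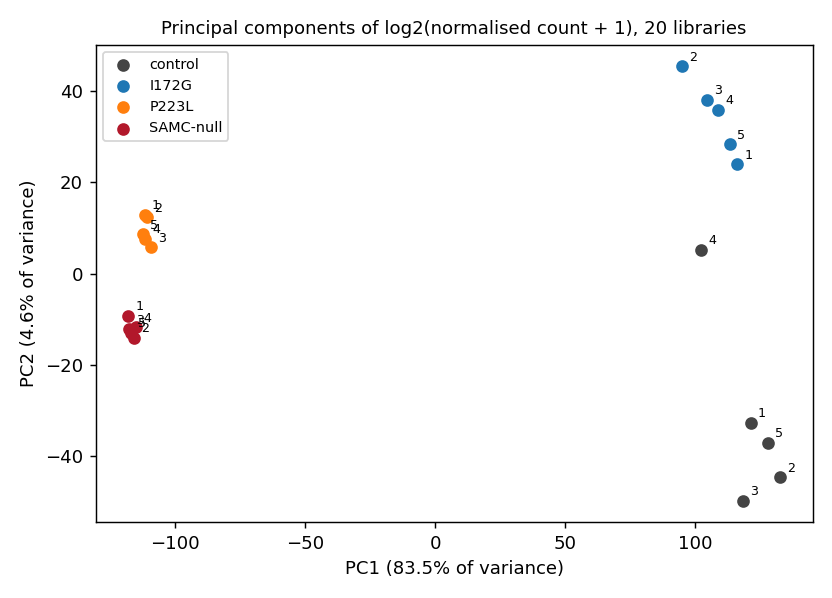
Scores of the 20 libraries on the first 2 principal components of log2(normalised count + 1) over 12639 genes, 1 point per library with its replicate number. The P223L and SAMC-null libraries sit at -118 to -109.33 on the horizontal axis and control replicate 4 at 5.26 on the vertical axis, above the other controls.

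The transcript of the SAM carrier itself, CG4743 (FBgn0039357; BDGP 6.54, chromosome 3R, 25679242 to 25680550), was measured at 125 ± 20.2 normalised counts in control, 171.5 ± 22.7 in I172G, 207 ± 24.6 in P223L and 112 ± 12.8 in SAMC-null (SD, n = 5). In P223L it rose by a log2 fold change of 0.73 ± 0.13 (SE) against control (adjusted p = 0.000218), with every P223L library above every control library. In I172G the log2 fold change was 0.46 ± 0.14 (adjusted p = 0.0285), and this call was lost when control replicate 1, 2 or 3 or I172G replicate 3 or 4 was left out, with adjusted p from 0.053 to 0.0675. In SAMC-null it did not pass the test (log2 fold change -0.14 ± 0.14, adjusted p = 0.346). The SAMC-null genotype carries an early frameshift and stop, so the transcript level does not check the label. In the authors' deposited table, which tests for changes beyond 2-fold, the log2 fold changes were 0.46, 0.73 and -0.15, each with an adjusted p of 1.

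The comparison of I172G with control asked what differs in the mild line. Transcripts of digestive enzymes of the gut and of the testis were lower in I172G, while replication-dependent histones and genes of DNA replication and the cell cycle were higher. None of these lists passed with an estimated correlation (lowest adjusted p = 0.59 with an estimated correlation). The lipase-like gene CG6296 (FBgn0039470; 3R, 27003236 to 27005469) fell from 28949 ± 6007 normalised counts in control to 394 ± 94.2 in I172G (SD, n = 5), a log2 fold change of -6.21 ± 0.19 (SE). Within 3 Mb of the carrier gene, where CG6296 lies, 86 of 659 genes were called with a change of at least 2-fold, against 809 of 11258 elsewhere. The digestive protease Jon99Ci fell from 3829 ± 1793 to 143 ± 67.8. Among the increases, w, which encodes a transporter subunit for eye pigment precursors and marks many transgenes, went from 10.7 ± 8.59 to 267 ± 186.

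The 10 largest decreases in I172G were in mthl8, CG6296, CG13566, CG4408, CG31091, CR43310, Jon99Ci, CG31089, CG11893 and CG6271. The receptor gene mthl8 was listed at 0 in all 5 I172G libraries against 190 ± 95.6 in control. Apart from mthl8, their log2 fold changes ran from -6.21 in CG6296 to -4.28 in CG6271. The 10 largest increases were in CG13670, CG43117, w, Sgs1, Yp2, CG3397, CG7329, Acp65Aa, hll and Drsl2. CG13670 went from 1.1 ± 0.0957 to 274 ± 95.5 (log2 fold change 6.96 ± 0.27, adjusted p = 9.11e-08). The yolk protein gene Yp2 rose by 3.66 ± 0.64, the glue gene Sgs1 by 4.24 ± 1.19, the cuticle protein gene Acp65Aa by 3.5 ± 0.39 and the drosomycin-like gene Drsl2 by 3.39 ± 0.92 (log2 fold change ± SE, n = 5 per group). For Sgs1 and Drsl2 the authors' deposited table gave log2 fold changes of 3.04 ± 0.88 and 4.93 ± 1.31 (SE) with adjusted p = 1 and 0.144, and Drsl2 missed the threshold with replicate number as a block (adjusted p = 0.0514).

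Of 37 digestive enzymes tested in I172G, 24 fell and 3 rose over all genes, and 25 fell and 6 rose adjusted over the list alone. Their median log2 fold change was -0.63 (camera adjusted p = 2.32e-06; adjusted p = 0.59 with an estimated correlation). Without control replicate 4, 23 fell and 5 rose. The maltases Mal-A3 and Mal-A4 had log2 fold changes of -2.07 ± 0.16 and -1.54 ± 0.14. Of 27 testis genes, 21 fell and 0 rose, 24 and 0 adjusted over the list alone, with a median of -0.94 (camera adjusted p = 8.3e-07; adjusted p = 0.82 with an estimated correlation). Mst84Dc and dj, both transcribed in the male germline, had -1.34 ± 0.25 and -1.06 ± 0.22. The mean log2 level of the testis list was 6.58 in control replicate 4, 7.34 to 7.77 in the other controls and 5.82 to 6.82 in I172G. Without control replicate 4, 25 testis genes were called lower.

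Of 20 genes of DNA replication and the cell cycle, 10 rose and 0 fell in I172G, 13 and 0 adjusted over the list alone, with a median of 0.26 (camera adjusted p = 4.64e-06; adjusted p = 0.59 with an estimated correlation). Cyclin A (CycA) rose by 0.42 ± 0.06 and the ribonucleotide reductase gene RnrL by 0.54 ± 0.08. Of 96 histone gene copies, 48 rose and 0 fell, 53 and 0 adjusted over the list alone, with a median of 0.65 (camera adjusted p = 9.02e-16; adjusted p = 0.59 with an estimated correlation). Reads are split between near-identical histone copies, so these counts are uncertain and the copies are not independent.

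Proteasome subunits split into 2 sets in I172G. Of 48 genes, 32 rose and 9 fell over all genes, 32 and 14 adjusted over the list alone (camera adjusted p = 2.15e-06 towards higher; adjusted p = 0.66 with an estimated correlation). Their median log2 fold change was 0.41 but their mean was -0.02. Of the 32 general subunits, 31 rose and 0 fell, with a median of 0.46, and Rpn1 rose by 0.63 ± 0.05. Of the 16 copies whose symbol ends in R or T, with or without a digit after it, 1 rose and 9 fell, with a median of -0.98. The testis-specific forms are among them. This split was made after the values were seen. Without control replicate 4, 32 of the 48 rose and 14 fell.

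Fatty acid oxidation in mitochondria had 7 of 9 genes higher and 0 lower in I172G, 8 and 0 adjusted over the list alone (median 0.31, camera adjusted p = 0.000393; adjusted p = 0.66 with an estimated correlation). Of 11 targets of the stress factor ATF4 and serine synthesis genes, 6 rose and 0 fell, 6 and 2 adjusted over the list alone (median 0.62, camera adjusted p = 0.0141; adjusted p = 0.59 with an estimated correlation). They included CG6287, at 1.34 ± 0.17, and asparagine synthetase (AsnS), at 1.16 ± 0.23. Genes of the tricarboxylic acid cycle were lower in 6 of 10 cases and higher in 0, 7 and 0 adjusted over the list alone (median -0.22, camera adjusted p = 0.0141; adjusted p = 0.83 with an estimated correlation). Without control replicate 4, 6 were lower and 1 higher (adjusted p = 0.0495). The citrate synthase gene kdn fell by 0.71.

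Nuclear complex I genes had 9 of 41 members lower and 0 higher in I172G, 8 and 0 adjusted over the list alone. Their median was -0.15 (camera adjusted p = 0.00912; adjusted p = 0.83 with an estimated correlation), and the camera call was lost without control replicate 4 (adjusted p = 0.0923). Cytosolic ribosomal proteins had a median of 0.05, with 3 of 91 higher and 2 lower, 0 and 2 adjusted over the list alone (camera adjusted p = 0.0461; adjusted p = 0.9 with an estimated correlation). That call was lost with replicate number as a block (adjusted p = 0.0631), while without control replicate 4 it had adjusted p = 0.00171, with 12 higher, 4 lower and a median of 0.08. The methionine cycle list, which holds the enzymes that make and use SAM, did not pass the test (6 higher and 3 lower of 13, 7 and 3 adjusted over the list alone, camera adjusted p = 0.19). Within it Sam-S, the SAM synthetase, fell by 0.92 and CG10623 rose by 0.93 ± 0.09. Larval cuticle genes named Lcp and the larval serum list did not pass (camera adjusted p = 0.0548 for each), but both passed without control replicate 4 (adjusted p = 0.00171 and 0.0492). With all libraries they had adjusted p = 0.83 and adjusted p = 0.66 with an estimated correlation. With replicate number as a block the Lcp list passed too (camera adjusted p = 0.0317). Lcp genes were higher in 4 of 15 cases, also adjusted over the list alone, and in 8 without control replicate 4. The glue list did not pass either (5 higher and 2 lower of 10, 7 and 2 adjusted over the list alone, median 1.79, camera adjusted p = 0.123; adjusted p = 0.83 with an estimated correlation).

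In the test of all 12253 genes with limma, 1789 rose and 2151 fell in I172G, and 220 of the former and 693 of the latter changed at least 2-fold. The excess of decreases was absent with median-ratio rescaling (1978 higher and 1978 lower) and with the filter of 50 (1758 and 1741). A total of 2213 genes had every library of 1 group above every library of the other, where chance gives 0.8% of genes. Without control replicate 4 the count was 5062 in place of 3940. A test against an absolute log2 fold change of 1 with limma's treat, added after seeing the data, called 19 genes higher and 42 lower, and the authors' deposited table, with its own test beyond that fold change, called 41 and 98.

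The comparison of P223L with control asked what differs in the line with the severe amino acid change. The storage proteins of the larval blood, made in the fat body, were almost absent: Lsp1beta (FBgn0002563; 2L, 898500 to 901316) went from 1162430 ± 112237 normalised counts in control to 26.1 ± 32.6 in P223L (SD, n = 5). Lsp2 (FBgn0002565; 3L, 12129393 to 12131869) went from 610563 ± 65088 to 13.3 ± 17.8. Larval cuticle, digestive enzyme, testis, muscle and cell cycle transcripts were lower as well. Neuronal genes, mitochondrial chaperones, iron-sulfur cluster assembly genes and the genes of the imaginal disc damage list were higher. With camera none of these lists passed once the correlation was estimated (lowest adjusted p = 0.22 with an estimated correlation). A difference in developmental stage from control was not tested, and the list results of P223L cannot be told apart from it.

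All 6 larval serum and fat body genes fell in P223L, also adjusted over the list alone, with a median log2 fold change of -15.62 (camera adjusted p = 0.000697; adjusted p = 0.35 with an estimated correlation). The 10 largest decreases were in Lsp1beta, Lsp1alpha, Lsp2, Obp99b, Fbp2, CG17105, Lcp9, Lsp1gamma, Lcp65Ab1 and Fbp1, from -16.53 ± 0.87 in Lsp1beta to -13.16 ± 0.69 in Fbp1 (log2 fold change ± SE). Lcp65Ab1 shares reads with a near-identical copy, so its value is uncertain. The 10 largest increases were in 28SrRNA-Psi:CR41609, phu, CG15068, CG42815, CG43117, CG12480, BaraA1, TwdlO, CG13215 and CG31300. The ribosomal RNA pseudogene 28SrRNA-Psi:CR41609 was at 356715 ± 88023 in P223L and 577 ± 581 in control, in libraries depleted of ribosomal RNA. The gene phu (FBgn0043791; 3R, 9494801 to 9496723) rose by 8.28 ± 0.37 and BaraA1, an antimicrobial peptide gene, by 7.59 ± 1.09. CG42815 was listed at 0 in all control libraries and at 231 ± 33.9 in P223L. TwdlO, a cuticle protein gene, rose by 7.36 ± 0.97, and among controls it stood at 288 in replicate 4 and at 2.29 to 7.02 in the others.

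Digestive enzymes were lower in 33 of 37 cases and higher in 3 in P223L, also adjusted over the list alone (median -2.14, camera adjusted p = 4.81e-07; adjusted p = 0.32 with an estimated correlation). The lipase gene mag had a log2 fold change of -4.63 ± 0.06 and the protease gene Jon66Ci of -5.39 ± 0.09. Testis genes were lower in 25 of 27 cases and higher in 1, also adjusted over the list alone (median -5.02, camera adjusted p = 7.46e-07; adjusted p = 0.4 with an estimated correlation), with ocn at -8.59 ± 0.27, and without control replicate 4 the counts were 26 and 0. Of 14 Lcp genes, 10 fell and 3 rose, also adjusted over the list alone (median -6.72, camera adjusted p = 0.00995; adjusted p = 0.49 with an estimated correlation). Of 48 Cpr cuticle genes, 28 fell and 11 rose, also adjusted over the list alone (median -1.75, camera adjusted p = 0.0129; adjusted p = 0.49 with an estimated correlation). Control replicate 4 had a mean log2 level of 8.13 on the Cpr list against 7.15 to 7.39 in the other controls. The glue list did not pass the test (median -7.58, 6 lower and 3 higher of 9, also adjusted over the list alone, camera adjusted p = 0.154).

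All 20 cell cycle genes fell in P223L, also adjusted over the list alone (median -1.70, camera adjusted p = 8.03e-07; adjusted p = 0.22 with an estimated correlation). The mitotic activators stg and CycB had log2 fold changes of -3.93 ± 0.10 and -3.79 ± 0.11. Histone copies fell in 59 of 86 cases and rose in 0, 56 and 0 adjusted over the list alone (median -1.98, camera adjusted p = 1.27e-06; adjusted p = 0.49 with an estimated correlation), again with reads split between copies. Without control replicate 4, 62 copies fell and 7 rose. Proteasome subunits were lower in 46 of 48 cases and higher in 0, also adjusted over the list alone (median -0.73, camera adjusted p = 1.2e-07; adjusted p = 0.35 with an estimated correlation), and the 32 general subunits had a median of -0.61. All 14 muscle genes fell, also adjusted over the list alone (median -1.07, camera adjusted p = 4.77e-05; adjusted p = 0.42 with an estimated correlation). Hemocyte genes were lower in 7 of 10 cases and higher in 1, also adjusted over the list alone (median -1.73, camera adjusted p = 0.0273; adjusted p = 0.49 with an estimated correlation), with Pxn at -3.16 ± 0.07.

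Neuronal genes were higher in 9 of 10 cases and lower in 0 in P223L, also adjusted over the list alone (median 2.40, camera adjusted p = 8.19e-05; adjusted p = 0.35 with an estimated correlation). The sodium channel gene para rose by 3.13 ± 0.10 and the synaptic vesicle gene nSyb by 2.43 ± 0.09. All 5 genes of the imaginal disc damage list rose, also adjusted over the list alone (median 1.54, camera adjusted p = 0.004; adjusted p = 0.31 with an estimated correlation), with the cytokine gene upd3 at 4.87 ± 0.19. RNA of whole larvae does not show in which tissue they rose. Of 18 insulin and starvation genes, 11 rose and 3 fell, also adjusted over the list alone (median 1.11, camera adjusted p = 0.0309; adjusted p = 0.31 with an estimated correlation). The insulin receptor gene InR rose by 3.14 ± 0.15 and ImpL2, whose product binds insulin-like peptides, by 2.22 ± 0.10.

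Among mitochondrial lists in P223L, chaperones and proteases had 9 of 10 genes higher and 0 lower, 10 and 0 adjusted over the list alone (median 0.71, camera adjusted p = 0.000292; adjusted p = 0.22 with an estimated correlation). Hsp22 rose by 4.33 ± 0.18 and Hsp60A by 1.34 ± 0.07. Iron-sulfur cluster assembly had 11 of 12 higher and 0 lower, also adjusted over the list alone (median 0.92, camera adjusted p = 0.000762; adjusted p = 0.35 with an estimated correlation), with the scaffold gene IscU at 1.13 ± 0.06. Mitochondrial ribosomal proteins were higher in 55 of 73 cases and lower in 1, 54 and 1 adjusted over the list alone (median 0.35, camera adjusted p = 7.17e-06; adjusted p = 0.49 with an estimated correlation). Mitochondrial DNA maintenance and transcription had 6 of 9 higher and 0 lower, also adjusted over the list alone (median 0.57, camera adjusted p = 0.0188; adjusted p = 0.31 with an estimated correlation), with the RNA polymerase gene mtRNApol at 1.64 ± 0.10.

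Subunits of the respiratory chain moved the other way in P223L, and the muscle list fell further than they did, at a median of -1.07. All 9 nuclear complex IV genes fell, also adjusted over the list alone (median -0.52, camera adjusted p = 0.0114; adjusted p = 0.49 with an estimated correlation). ATP synthase genes were lower in 11 of 12 cases and higher in 0, 12 and 0 adjusted over the list alone (median -0.34, camera adjusted p = 0.0226; adjusted p = 0.56 with an estimated correlation). Nuclear complex I had 25 of 40 lower and 1 higher, also adjusted over the list alone (median -0.31, camera adjusted p = 0.0129; adjusted p = 0.66 with an estimated correlation), and 24 lower and 2 higher without control replicate 4. Mitochondrially encoded mRNAs did not pass the test (5 higher and 1 lower of 11, also adjusted over the list alone, camera adjusted p = 0.166), nor did nuclear complex II (camera adjusted p = 0.391) and complex III (camera adjusted p = 0.0646).

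Glycolysis genes fell in 11 of 13 cases and rose in 1 in P223L, also adjusted over the list alone (median -1.13, camera adjusted p = 0.00155; adjusted p = 0.4 with an estimated correlation). The muscle list fell by about as much, at a median of -1.07. The 2-oxoacid dehydrogenase and glycine cleavage list had 10 of 12 lower and 1 higher, 11 and 1 adjusted over the list alone (median -0.51, camera adjusted p = 0.0129; adjusted p = 0.49 with an estimated correlation), with the glycine cleavage gene ppl at -1.66 ± 0.07. Tricarboxylic acid cycle genes were lower in 8 of 10 cases and higher in 0, also adjusted over the list alone (median -0.31, camera adjusted p = 0.0422; adjusted p = 0.49 with an estimated correlation). Cytosolic ribosomal proteins were higher in 82 of 91 cases and lower in 7, also adjusted over the list alone (median 0.39, camera adjusted p = 2.64e-09; adjusted p = 0.49 with an estimated correlation). Ribosome biogenesis had 10 of 11 higher and 0 lower, also adjusted over the list alone (median 0.82, camera adjusted p = 0.000393; adjusted p = 0.4 with an estimated correlation). The ATF4 and serine list had 8 of 11 higher and 2 lower, also adjusted over the list alone (median 0.71, camera adjusted p = 0.0226; adjusted p = 0.41 with an estimated correlation). The methionine cycle list did not pass (7 higher and 5 lower of 13, also adjusted over the list alone, camera adjusted p = 0.58), while in it Cbs rose by 2.24 ± 0.07 and Gnmt, which uses SAM to methylate glycine, fell by 1.98.

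Over 12208 genes tested with limma, 4435 rose and 5171 fell in P223L, and 1644 and 2847 of them changed at least 2-fold. The groups did not overlap for 8325 genes, where chance gives 0.8%. With limma's treat, added after seeing the data, 1165 genes were called higher and 2303 lower, and the authors' deposited table called 1170 and 2616.

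**Figure D2:**
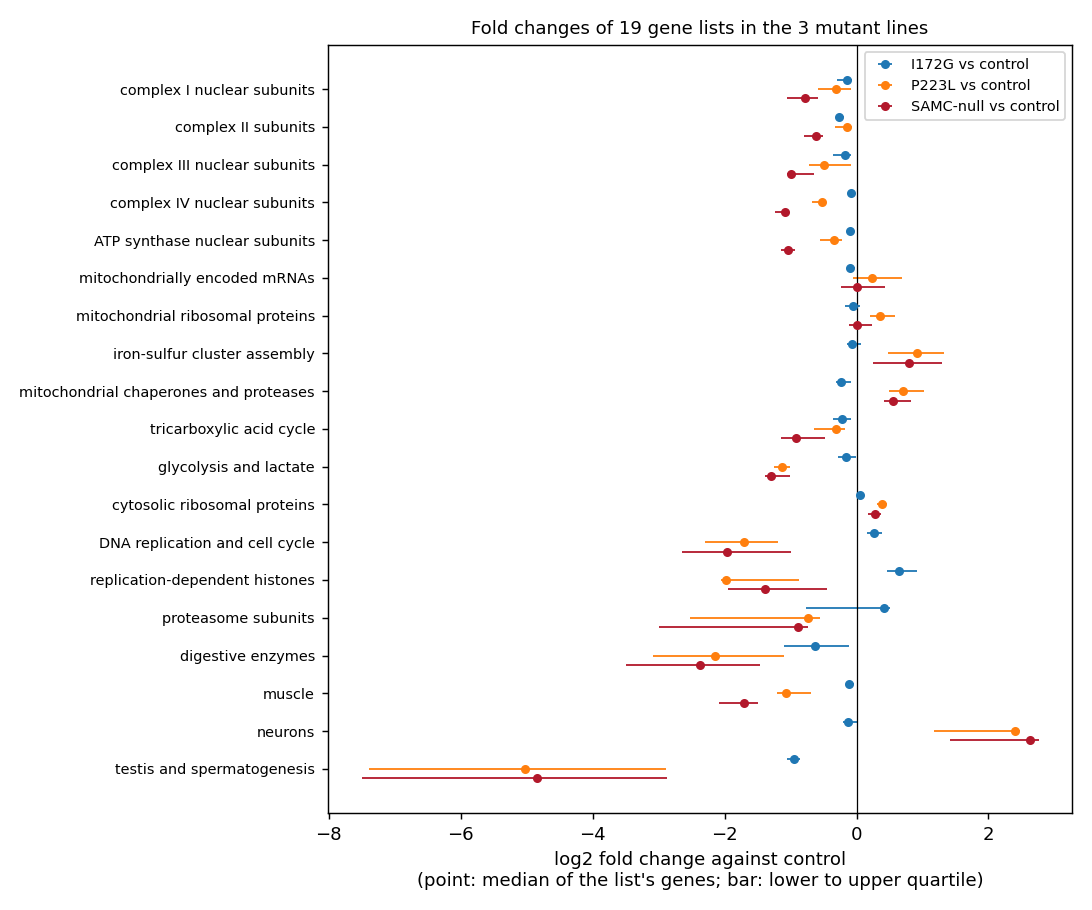
Median log2 fold change against control of 19 gene lists (points) with the lower to upper quartile of their genes (bars), for I172G, P223L and SAMC-null with 5 libraries per group. The testis list lies at -0.94, -5.02 and -4.84, and the neuron list at -0.13, 2.40 and 2.63.

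The comparison of SAMC-null with control asked what differs in the null line. As in P223L, the larval serum proteins were almost absent, with Lsp1alpha at 787415 ± 99255 normalised counts in control and 5.04 ± 6.21 in SAMC-null (SD, n = 5). Respiratory chain, tricarboxylic acid cycle, muscle and cell cycle transcripts were lower, and neuronal, heat shock, insulin and starvation, and iron-sulfur cluster assembly transcripts were higher. All of these list calls were lost when the correlation was estimated (lowest adjusted p = 0.12 with an estimated correlation). As in P223L, the list results cannot be told apart from an untested difference in developmental stage. The gene y, which is needed for dark cuticle pigment, went from 11.2 ± 12.0 to 1009 ± 63.0, and w from 10.7 ± 8.59 to 1738 ± 596.

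The 10 largest increases in SAMC-null were in CG42815, CG15068, CG32188, CG32189, CG13215, CG43117, w, phu, y and CG7227. CG42815 (3L, 17791079 to 17791486) was listed at 0 in all control libraries and at 410 ± 52.5 in SAMC-null, and the others had log2 fold changes from 8.13 ± 0.23 in CG15068 to 7.12 ± 0.24 in CG7227. The 10 largest decreases were in Lsp1alpha, Lsp1beta, Lsp2, Obp99b, Fbp2, Lcp3, Lcp9, CG17105, Fbp1 and Lcp65Ab1, from -17.47 ± 0.47 in Lsp1alpha to -13.24 ± 0.32 in Lcp65Ab1. All 6 larval serum and fat body genes fell, also adjusted over the list alone (median -15.70, camera adjusted p = 0.000514; adjusted p = 0.32 with an estimated correlation).

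Nuclear genes of all 5 respiratory complexes were lower in SAMC-null. Complex I had 37 of 40 lower and 0 higher, also adjusted over the list alone (median -0.78, camera adjusted p = 3.74e-07; adjusted p = 0.35 with an estimated correlation). All 4 genes of complex II (median -0.61, camera adjusted p = 0.0414), all 12 of complex III (median -0.99, camera adjusted p = 0.00206), all 9 of complex IV (median -1.09, camera adjusted p = 0.000594) and all 12 of ATP synthase (median -1.04, camera adjusted p = 9.4e-05) fell, also adjusted over the list alone. Each of these 4 lists had adjusted p = 0.35 with an estimated correlation. The muscle list fell with them, at a median of -1.71. COX6B and ATPsynO had log2 fold changes of -1.34 ± 0.04 and -1.37 ± 0.06. Mitochondrially encoded mRNAs did not pass the test (median 0.01, 4 higher and 4 lower of 11, also adjusted over the list alone, camera adjusted p = 0.811). Mitochondrial ribosomal proteins did not pass either (median 0.01, 19 higher and 11 lower of 73, 15 and 7 adjusted over the list alone, camera adjusted p = 0.37).

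All 10 tricarboxylic acid cycle genes fell in SAMC-null, also adjusted over the list alone (median -0.91, camera adjusted p = 0.00111; adjusted p = 0.35 with an estimated correlation), with the malate dehydrogenase gene Mdh2 at -1.49 ± 0.04. Glycolysis genes were lower in 12 of 13 cases and higher in 1, also adjusted over the list alone (median -1.29, camera adjusted p = 0.000838; adjusted p = 0.35 with an estimated correlation). The muscle list fell further than both lists, at a median of -1.71. The 2-oxoacid dehydrogenase and glycine cleavage list had 10 of 12 lower and 0 higher, also adjusted over the list alone (median -0.98, camera adjusted p = 0.00158; adjusted p = 0.32 with an estimated correlation). Iron-sulfur cluster assembly had 9 of 12 higher and 1 lower, also adjusted over the list alone (median 0.80, camera adjusted p = 0.00734; adjusted p = 0.35 with an estimated correlation), with IscU at 1.30 ± 0.06. Mitochondrial chaperones and proteases had 9 of 10 higher and 1 lower, also adjusted over the list alone (median 0.55, camera adjusted p = 0.00283; adjusted p = 0.27 with an estimated correlation).

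All 20 cell cycle genes fell in SAMC-null, also adjusted over the list alone (median -1.96, camera adjusted p = 1.74e-06; adjusted p = 0.12 with an estimated correlation), with polo at -3.64 ± 0.12. Histone copies were lower in 55 of 83 cases and higher in 9, also adjusted over the list alone (median -1.38, camera adjusted p = 5.79e-05; adjusted p = 0.41 with an estimated correlation). Proteasome subunits were lower in 47 of 48 cases and higher in 1, also adjusted over the list alone (median -0.89, camera adjusted p = 5.1e-08; adjusted p = 0.32 with an estimated correlation). All 14 muscle genes fell, also adjusted over the list alone (median -1.71, camera adjusted p = 1.78e-06; adjusted p = 0.35 with an estimated correlation), with the myosin light chain gene Mlc2 at -2.13 ± 0.06. Digestive enzymes were lower in 32 of 37 cases and higher in 2, also adjusted over the list alone (median -2.37, camera adjusted p = 1.8e-07; adjusted p = 0.14 with an estimated correlation). Testis genes were lower in 25 of 27 cases and higher in 1, also adjusted over the list alone (median -4.84, camera adjusted p = 1.74e-06; adjusted p = 0.35 with an estimated correlation).

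The Lcp and Cpr cuticle lists, the glue list and ecdysone synthesis were lower too in SAMC-null. Lcp genes fell in 10 of 14 cases and rose in 1 (median -7.53, camera adjusted p = 0.00211; adjusted p = 0.38 with an estimated correlation), and Cpr genes fell in 30 of 49 and rose in 12 (median -1.49, camera adjusted p = 0.00734; adjusted p = 0.38 with an estimated correlation), in both lists also adjusted over the list alone. The Lcp counts were 10 and 4 without control replicate 4. Glue genes were lower in 7 of 9 cases and higher in 1, also adjusted over the list alone (median -7.54, camera adjusted p = 0.0386; adjusted p = 0.35 with an estimated correlation), and Sgs5 was listed at 0 in all SAMC-null and P223L libraries. Of 7 genes of ecdysone synthesis, the making of the moulting hormone, 6 fell and 1 rose, also adjusted over the list alone (median -1.92, camera adjusted p = 0.0414; adjusted p = 0.35 with an estimated correlation), with spok at -3.77 ± 0.20. That camera call was lost without control replicate 4 (adjusted p = 0.0624). Twdl cuticle genes (9 higher and 4 lower of 15, 10 and 5 adjusted over the list alone, camera adjusted p = 0.503), ecdysone response (8 and 5 of 14, camera adjusted p = 0.323) and juvenile hormone genes (4 and 4 of 8, camera adjusted p = 0.766) did not pass, the last 2 with the same counts adjusted over the list alone. Hemocyte genes were lower in 9 of 11 cases and higher in 1, also adjusted over the list alone (median -1.40, camera adjusted p = 0.0344; adjusted p = 0.35 with an estimated correlation).

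Neuronal genes were higher in 9 of 10 cases and lower in 0 in SAMC-null, also adjusted over the list alone (median 2.63, camera adjusted p = 8.75e-05; adjusted p = 0.35 with an estimated correlation), with the active zone gene brp at 2.76 ± 0.11. Heat shock genes were higher in 9 of 15 cases and lower in 2, also adjusted over the list alone (median 1.13, camera adjusted p = 0.0414; adjusted p = 0.5 with an estimated correlation). Hsp70Ba, whose reads are shared with near-identical copies, rose by 6.64 ± 0.51. Antimicrobial peptides were higher in 6 of 10 cases and lower in 0, also adjusted over the list alone (median 1.35, camera adjusted p = 0.0375; adjusted p = 0.35 with an estimated correlation), with DptB at 4.82 ± 0.49. All 5 genes of the disc damage list rose, in a tissue not known here, also adjusted over the list alone (median 2.09, camera adjusted p = 0.00283; adjusted p = 0.27 with an estimated correlation). Insulin and starvation genes were higher in 12 of 18 cases and lower in 3, also adjusted over the list alone (median 1.18, camera adjusted p = 0.0132; adjusted p = 0.27 with an estimated correlation), with the lipase gene bmm at 2.41 ± 0.13.

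Cytosolic ribosomal proteins were higher in 78 of 91 cases and lower in 7 in SAMC-null (median 0.28, camera adjusted p = 8.57e-07; adjusted p = 0.45 with an estimated correlation). Ribosome biogenesis had 10 of 11 higher and 0 lower (median 0.71, camera adjusted p = 0.00239; adjusted p = 0.35 with an estimated correlation), and the ATF4 and serine list 7 of 11 higher and 1 lower (median 0.57, camera adjusted p = 0.0414; adjusted p = 0.35 with an estimated correlation). The counts of these 3 lists were the same adjusted over the list alone. The methionine cycle list did not pass (4 higher and 5 lower of 13, also adjusted over the list alone, camera adjusted p = 0.672), and without control replicate 4 it had 8 higher and 5 lower (adjusted p = 0.492), while in it Sam-S rose by 0.89 ± 0.09 and Cbs by 1.87 ± 0.07.

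Over 12252 genes tested with limma, 4677 rose and 5329 fell in SAMC-null, and 1879 and 3079 of them changed at least 2-fold. The groups did not overlap for 8809 genes, where chance gives 0.8%. With limma's treat, added after seeing the data, 1358 genes were called higher and 2535 lower, and the authors' deposited table called 1352 and 2811.

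Most genes that changed in P223L changed in the same direction in SAMC-null. Of 12152 genes tested in both, 3990 rose in both lines, 4794 fell in both and 101 changed in opposite directions, where independent lists would share 1678 and 2263. Both comparisons use the same controls. With separate controls, 2 for P223L and 3 for SAMC-null or the reverse, 8167 and 8290 genes were shared in place of 8784. A difference in developmental stage from control that both lines share would also give shared calls with separate controls. It was not tested, so the overlap does not tell the cause. The covariance of the log2 fold changes across genes was 4.078, against a mean of 0.017 in 20 simulations of unchanged groups with shared controls, which shared 0 calls. The simulations used 11700 genes drawn independently of each other, so they lack the variation that genes share between real libraries. Unchanged groups give almost no calls and small fold changes. The 0 shared calls and the low covariance were thus close to fixed in advance and add no support. Pearson's r of the log2 fold changes across genes was 0.967 for the 2 lines. Shared controls alone gave a mean r of 0.51 in the simulations, and with separate controls r was 0.954 and 0.959. For I172G, a comparison of lists added after seeing the data found 477 genes higher and 1342 lower in both I172G and P223L, where independent lists would share 630 and 923, and 1508 genes in opposite directions. With 2 controls for I172G and 3 for P223L, 288 were higher and 1165 lower in both, where independent lists would share 444 and 726, and 1123 were opposite. With 3 and 2 controls, 204 were higher and 346 lower in both, where independent lists would share 284 and 282, and 709 were opposite. How many opposite genes independent lists would give was not computed, so the opposite counts of I172G do not by themselves show discordance.

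The direct comparison of P223L with SAMC-null asked where the severe lines differ. Muscle and respiratory chain transcripts were higher in P223L, and heat shock transcripts were lower, but none of these lists passed with an estimated correlation (muscle adjusted p = 0.18, complex I adjusted p = 0.23 and heat shock adjusted p = 0.47 with an estimated correlation). The muscle actin gene Act57B was higher by 1.24 ± 0.04 and Mhc by 1.19 ± 0.05 (log2 fold change ± SE, n = 5 per group). The sperm aminopeptidase gene S-Lap1 (FBgn0035915; 3L, 8617235 to 8619474) was at 10.4 ± 2.53 normalised counts in P223L and 958 ± 235 in SAMC-null, and mthl8 at 1.04 ± 1.32 and 342 ± 42.3. The carrier transcript CG4743 was higher in P223L by 0.88 ± 0.10 (adjusted p = 5.21e-06).

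The 5 largest differences towards P223L were in Atg8b, CG5623, CG14317, nsr and CG5050, from 6.85 ± 0.30 in Atg8b, a paralogue of an autophagy gene, to 5.31 ± 0.16 in CG5050. The 5 largest towards SAMC-null were in mthl8, CG7707, S-Lap1, CG12470 and CG14644, and CG7707 was listed at 0 in all P223L libraries and at 115.1 ± 35.6 in SAMC-null. Muscle genes were higher in P223L in 13 of 14 cases and lower in 0, also adjusted over the list alone (median 0.76, camera adjusted p = 5.31e-12; adjusted p = 0.18 with an estimated correlation). Complex I had 34 of 37 higher and 0 lower, also adjusted over the list alone (median 0.49, camera adjusted p = 2.23e-15; adjusted p = 0.23 with an estimated correlation). All 12 ATP synthase genes were higher, also adjusted over the list alone (median 0.68, camera adjusted p = 9.16e-11; adjusted p = 0.23 with an estimated correlation), as were all 9 of complex IV (median 0.59, camera adjusted p = 6.74e-07; adjusted p = 0.23 with an estimated correlation). Mitochondrial ribosomal proteins were higher in 62 of 73 cases and lower in 0, 65 and 0 adjusted over the list alone (median 0.34, camera adjusted p = 7.35e-15; adjusted p = 0.23 with an estimated correlation).

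Tricarboxylic acid cycle genes were higher in P223L than in SAMC-null in 9 of 10 cases and lower in 0, also adjusted over the list alone (median 0.54, camera adjusted p = 4.49e-07; adjusted p = 0.23 with an estimated correlation). Xenobiotic cytochrome P450 genes were higher in 26 of 51 cases and lower in 9, also adjusted over the list alone (median 0.22, camera adjusted p = 0.000204; adjusted p = 0.095 with an estimated correlation). Of 10 Lcp genes, 7 were higher and 0 lower, also adjusted over the list alone (median 0.87, camera adjusted p = 0.000179; adjusted p = 0.23 with an estimated correlation). Heat shock genes were lower in 10 of 15 cases and higher in 0, also adjusted over the list alone (median -1.08, camera adjusted p = 0.00539; adjusted p = 0.47 with an estimated correlation). Folate and purine synthesis had 7 of 13 lower and 2 higher, also adjusted over the list alone (median -0.15, camera adjusted p = 0.00331; adjusted p = 0.23 with an estimated correlation), with Prat2 at -1.87 ± 0.07. Neuronal genes were lower in 8 of 10 cases and higher in 0, also adjusted over the list alone (median -0.25, camera adjusted p = 0.0109; adjusted p = 0.45 with an estimated correlation). Disc damage genes were lower in 3 of 5 cases and higher in 0, 4 and 0 adjusted over the list alone (median -0.61, camera adjusted p = 0.00518; adjusted p = 0.23 with an estimated correlation).

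A total of 30 of 42 lists passed camera between P223L and SAMC-null, 24 higher and 6 lower in P223L, and 0 passed with an estimated correlation, where the lowest adjusted p was 0.095. Over 11168 genes tested with limma, 2500 were higher and 2798 lower in P223L, and 262 and 230 of them differed at least 2-fold. With limma's treat, added after seeing the data, 127 were called higher and 65 lower.

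The direct comparison of I172G with P223L asked where the mild and the severe amino acid change differ. Larval serum genes were higher in I172G by a median log2 fold change of 16.25, with all 6 genes higher, also adjusted over the list alone (camera adjusted p = 0.000766; adjusted p = 0.44 with an estimated correlation). The 5 largest differences towards I172G were in Lsp1alpha, Lsp1beta, Lsp2, Fbp2 and Fbp1, from 16.63 ± 0.56 in Lsp1alpha to 15.79 ± 0.45 in Fbp1 (SE, n = 5 per group). The 5 largest towards P223L were in 28SrRNA-Psi:CR41609, CG12480, phu, CG15068 and TwdlO, from -10.26 ± 0.39 to -8.70 ± 0.47.

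All 20 cell cycle genes were higher in I172G than in P223L, also adjusted over the list alone (median 2.06, camera adjusted p = 1.71e-07; adjusted p = 0.21 with an estimated correlation). Histone copies were higher in 86 of 94 cases and lower in 0, also adjusted over the list alone (median 2.51, camera adjusted p = 1.56e-10; adjusted p = 0.44 with an estimated correlation). Proteasome subunits were higher in 43 of 46 cases and lower in 0, also adjusted over the list alone (median 1.16, camera adjusted p = 1.56e-10; adjusted p = 0.44 with an estimated correlation). Testis genes were higher in 20 of 24 cases and lower in 1, also adjusted over the list alone (median 4.38, camera adjusted p = 9.29e-05; adjusted p = 0.46 with an estimated correlation). Neuronal genes were lower in 9 of 10 cases and higher in 0, also adjusted over the list alone (median -2.48, camera adjusted p = 9.29e-05; adjusted p = 0.36 with an estimated correlation). All 10 mitochondrial chaperones and proteases were lower, also adjusted over the list alone (median -1.04, camera adjusted p = 0.000602; adjusted p = 0.37 with an estimated correlation), and iron-sulfur cluster assembly had 10 of 12 lower and 0 higher, also adjusted over the list alone (median -1.19, camera adjusted p = 0.00113; adjusted p = 0.46 with an estimated correlation). All 9 nuclear complex IV genes were higher, also adjusted over the list alone (median 0.51, camera adjusted p = 0.0424; adjusted p = 0.65 with an estimated correlation), as were all 14 muscle genes (median 0.94, camera adjusted p = 0.000211; adjusted p = 0.49 with an estimated correlation). Nuclear complex I did not pass (21 higher and 5 lower of 38, 18 and 5 adjusted over the list alone, camera adjusted p = 0.28), nor did complex II (camera adjusted p = 0.877), complex III (camera adjusted p = 0.532) and ATP synthase (camera adjusted p = 0.14).

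A total of 20 of 43 lists passed camera between I172G and P223L, 12 higher and 8 lower in I172G, and 0 passed with an estimated correlation, where the lowest adjusted p was 0.21. CG4743 was lower in I172G by a log2 fold change of -0.27 ± 0.11 (adjusted p = 0.0405), and this call was lost with replicate number as a block (adjusted p = 0.0913) and without I172G replicate 1, 2 or 5 or P223L replicate 1, 2, 4 or 5 (adjusted p from 0.0506 to 0.105). Over 12029 genes tested with limma, 5158 were higher and 4567 lower in I172G, and 2724 and 1911 of them differed at least 2-fold. With limma's treat, added after seeing the data, 2170 were called higher and 1342 lower.

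Against control, 10 of 43 lists passed camera in I172G, 26 of 43 in P223L and 30 of 43 in SAMC-null, and 0 passed in each with an estimated correlation, where the lowest adjusted p was 0.59, 0.22 and 0.12.

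**Figure D3:**
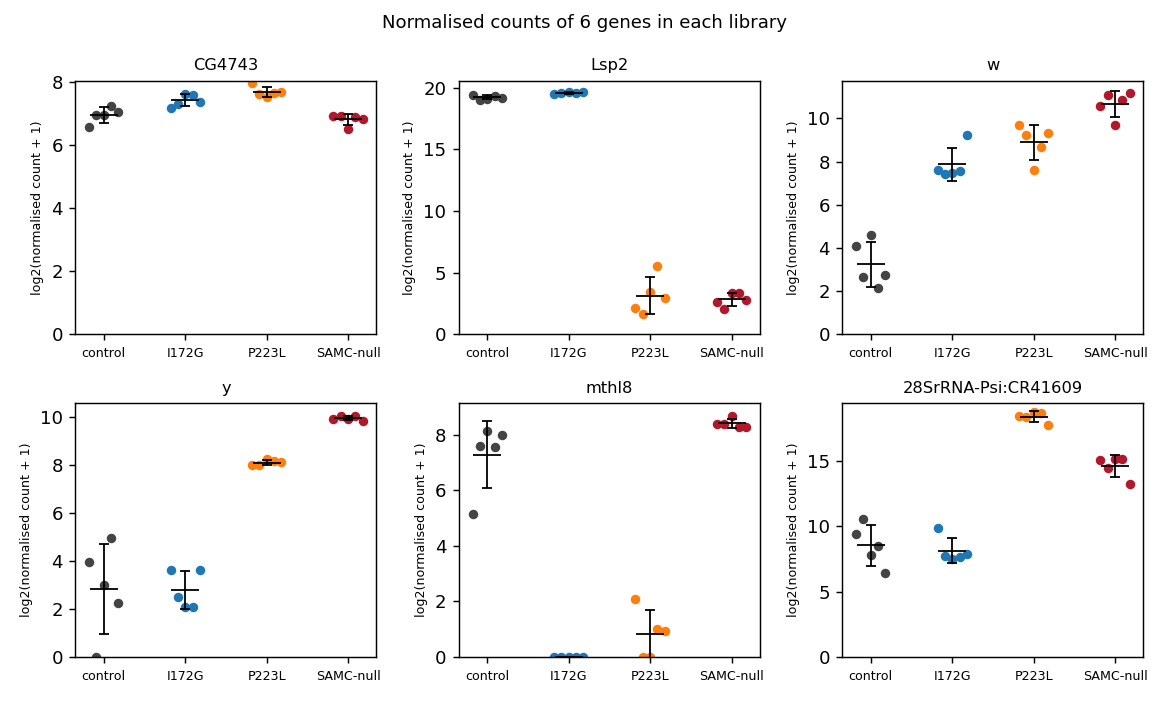
Level of 6 genes in each library as log2(normalised count + 1), by group, with 1 point per library and a bar for the mean ± SD of 5 libraries. The gene mthl8 lies at 0 in all I172G libraries, Lsp2 is near the floor in P223L and SAMC-null, and y is highest in SAMC-null, at 926 to 1081 normalised counts.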

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

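All tests of explanations in this part were chosen after the results were seen. A library was singled out when the gap between the highest or lowest of the 5 libraries of a group and its nearest neighbour exceeded 0.71 of the group's range, which chance gives in about 1 of 20 groups. For single genes the gap and range were taken on log2(value + 1), while the values printed below are normalised counts. Of 301 groups of values looked at, 25 met this, where chance would give about 15, and none of the 16 groups of library measures (total, reads, top genes, genes detected) was among them.

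Control replicate 4 held 4 of these values. Its mean log2 level was 8.13 on the Cpr cuticle list (other controls 7.15 to 7.39) and 6.65 on the Twdl cuticle list (4.16 to 4.56), and its normalised counts were 288 for TwdlO (2.29 to 7.02) and 27.2 for CG7227 (9.47 to 12.7). In control replicate 1, mthl8 was at 34.5 (190 to 279), and in control replicate 3 the complex III list was at 10.29 (10.61 to 10.65).

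In the I172G line, w was at 599 in replicate 5 (173 to 194 in the others), CG11893 at 49.2 in replicate 2 (27.2 to 30.0), 28SrRNA-Psi:CR41609 at 951 in replicate 1 (182 to 239) and the ecdysone response list at 10.61 in replicate 1 (9.81 to 10.03).

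In P223L, replicate 1 was highest on the glycolysis list at 13.62 (13.5 to 13.54) and on the ATF4 and serine list at 10.98 (10.82 to 10.86), and lowest for CG14317 at 102 (157 to 180). Replicate 4 was lowest for BaraA1 at 181 (831 to 1167), highest for Lsp1gamma at 157 (52.8 to 64.9) and highest on the testis list at 2.76 (2.42 to 2.51). Lcp65Ab1 was at 0.0 in replicate 2 (19.3 to 32.4), and ribosome biogenesis at 10.06 in replicate 3 (10.1 to 10.12).

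In SAMC-null, replicate 1 was highest on the mitochondrial ribosomal protein list at 8.55 (8.43 to 8.45) and the mitochondrial chaperone list at 11.89 (11.75 to 11.77), and lowest on the neuron list at 11.11 (11.21 to 11.22). Histones were at 6.12 in replicate 2 (5.86 to 5.93), CG4743 at 90.4 in replicate 3 (113 to 121), and replicate 4 held Lsp1beta at 40.6 (3.0 to 5.38) and the Cpr list at 5.77 (5.45 to 5.54).

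Other splits of the 10 libraries of each comparison into groups of 5 were counted, 100 of the 126 being drawn with the real one among them. In each of the 5 comparisons 1 split, the real one, gave as many genes, which is the lowest number possible here. Where many genes differ, mixed splits mostly call few genes, so this outcome was close to fixed in advance. It was less so in I172G against control, where the highest of the other splits called 2194 genes. The median over the other splits was 0 there. A difference of culture, stage or batch shared by a whole group would give the same result, so the splits do not tell the cause. The real count and the highest of the other splits were 3940 and 2194 for I172G against control, 9606 and 1 for P223L, 10006 and 1 for SAMC-null, 5298 and 1 for P223L against SAMC-null, and 9725 and 1 for I172G against P223L.

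The lower testis transcripts in I172G (21 of 27 called, median log2 fold change -0.94) were set against 2 explanations. An earlier larval stage in I172G cannot be told apart from an effect of the mutation: the 10 glue genes, most of which come on late in larval life, had a median log2 fold change of 1.79 with an SD of 1.59, but 5 were called higher and 2 lower, and the list did not pass camera (adjusted p = 0.123; adjusted p = 0.83 with an estimated correlation). Part of the values run against an earlier stage: the 6 Sgs glue genes tested had higher means in I172G, such as Sgs3 at 5937 ± 3358 against 1635 ± 1149 and Sgs7 at 20789 ± 10880 against 7517 ± 5722, the fat body gene Fbp1 was at 195960 ± 114328 against 42569 ± 39356, and 3 larval serum and fat body genes were called higher and 0 lower of 6. A smaller share of male larvae cannot be told apart from smaller testes in each male. The 20 members at least 8-fold lower in SAMC-null had an SD of log2 fold changes 0.8 times their median standard error in I172G, with values from -1.59 to -0.8. The members vary together between libraries (estimated correlation 0.677), so any cause acting on all of them would give a low ratio. A later larval stage in I172G was not tested and stays open. Among controls, replicate 4 had the highest mean log2 level of the glue list, at 10.99 against 8.55 to 10.76. It also had the lowest level of the testis list, at 6.58 against 7.34 to 7.77. The sex of the larvae is not given in the labels, and an effect of the mutation stays open, untested.

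Nuclear respiratory chain transcripts in SAMC-null (74 of 77 lower, median log2 fold change -0.93) were set against 2 explanations. A like fall of all mitochondrial transcripts is argued against by the mitochondrial ribosomal proteins, whose median was 0.01 with an SD of 0.28 over 73 genes. The mitochondrially encoded mRNAs ran from -0.89 to 0.73. Fewer mitochondria stays open, because transcript levels in whole larvae do not count mitochondria. Ribosomal transcripts may also follow a wider change, as ribosome biogenesis genes had a median of 0.71 in the same line. A smaller share of muscle, a tissue rich in respiratory chain transcripts, cannot be told apart from a change within cells, because the muscle list fell with them, at a median of -1.71 in SAMC-null and -1.07 in P223L, where the respiratory chain median was -0.39. A difference in developmental stage between the severe lines and control was not tested and stays open, as does the loss of the carrier itself. The larval serum list (median -15.62 in P223L and -15.7 in SAMC-null) and the glue list (-7.58 and -7.54) fell in both. Of 9 glue genes, 6 and 7 were lower and 3 and 1 higher. Most glue genes come on late in larval life, so an earlier stage of the severe larvae would lower them. No list result of these lines against control, the cell cycle, muscle, neuron, testis and cuticle results among them, can be told apart from such a difference.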

How the results depend on the processing

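Of the tests here, limma's treat and the lists with rescaling or without control replicate 4 were chosen after the results were seen, and the rest were planned. All 6 counts (5 comparisons and the shared calls) stayed within 1.5 times their value with pseudocounts of 0.5 and 4, no filter, a filter of 50, median-ratio rescaling, 1 fit of all groups, a replicate block and each library left out. Against an absolute log2 fold change of 1, treat called 61 genes in I172G, 3468 in P223L, 3893 in SAMC-null, 192 between P223L and SAMC-null and 3512 between I172G and P223L, with 3198 shared calls. The authors' adjusted p, from the same kind of test, called 139, 3786 and 4163 against control, with 3439 shared. By construction both leave out smaller changes. With each library left out the counts were 2751 to 5062 for I172G (the highest without control replicate 4), 9318 to 9711 for P223L, 9724 to 10111 for SAMC-null, 4746 to 5281 between P223L and SAMC-null, 9499 to 9722 between I172G and P223L, and 8569 to 8837 for the shared calls. With replicate number as a block they were 2687, 9385, 9806, 5438, 9518 and 8560, and residuals of equally numbered libraries correlated at -0.21 to 0.1. No result past the threshold changed its direction. Among lists past it in neither fit, the block turned folate and purine synthesis in SAMC-null and the ATF4 and serine list between P223L and SAMC-null from higher to lower. Leaving out control replicate 4 turned mitochondrial ribosomal proteins, iron-sulfur cluster assembly, cytochrome P450 genes and disc damage genes in I172G from lower to higher. The balance of calls depended on the setting. With the filter of 50, 4143 genes were higher and 4131 lower in P223L, 4335 and 4308 in SAMC-null, and 4198 and 4194 in I172G against P223L. Between P223L and SAMC-null 2642 were higher and 2591 lower with rescaling, and 1881 and 1852 with 1 fit of all groups. With an estimated correlation 116 of 214 list results fell short of the threshold and 98 stayed on their side. The block added calls for Lcp genes in I172G (adjusted p = 0.0317), antimicrobial peptides in P223L (0.0432), and glycolysis and ecdysone response between P223L and SAMC-null (0.0335 and 0.0409). Of 85 named results, 8 missed the threshold with treat and 2 with the block, and with the authors' adjusted p, which covers fewer of them, 55 stayed on their side of it and 4 missed it. Yp2 and hll were among the 8 with treat (adjusted p = 0.128 and 0.223); the cause was not tested. The DESeq2 test and a count test on whole reads were not run, because part of the low values did not lie near whole reads. The threshold variants did not apply to tables with values per library, and the authors' adjusted p has no table here for the comparisons between mutants. Depth was not varied, and simulated 1.5-fold changes were recovered in 62 to 74% of cases.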

Other observations

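All tests of explanations in this part were chosen after the results were seen. Yp1, Yp3 and the ribosomal RNA genes fall outside the rule for named genes and were chosen after their values were seen. The 3 yolk protein genes were higher in I172G and far lower in both severe lines. Yp3 was at 815 ± 353 normalised counts in control, 5586 ± 1895 in I172G, 3.75 ± 2.51 in P223L and 8.31 ± 4.71 in SAMC-null (SD, n = 5), and Yp1 at 141 ± 102, 532 ± 274, 3.72 ± 2.36 and 4.56 ± 2.14. With limma, Yp1, Yp2 and Yp3 had log2 fold changes of 2.00, 3.66 and 2.83 in I172G (adjusted p = 0.0278, 0.00232 and 0.000105). The fat body gene Fbp1 was at 42569 ± 39356 in control and 195960 ± 114328 in I172G. The dosage compensation gene msl-2 was at 676 ± 118 in control, 557 ± 49.3 in I172G, 814 ± 50.5 in P223L and 747 ± 40.7 in SAMC-null, and it did not pass the test in I172G (log2 fold change -0.26, adjusted p = 0.12). Its transcript level does not give the share of males.

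Some genes differed strongly in level between the lines, and a few were listed at 0 throughout a group. The gene w was at 10.7 ± 8.59 in control, a white-eyed background, and at 267 ± 186, 533 ± 241 and 1738 ± 596 in I172G, P223L and SAMC-null. The gene y was at 11.2 ± 12.0 in control, 6.76 ± 4.17 in I172G, 277 ± 20.9 in P223L and 1009 ± 63.0 in SAMC-null. CG43117 (3R, 26454794 to 26455112) was at 48.5 ± 85.4 in control and 1813 ± 330, 4195 ± 198 and 3221 ± 361 in the 3 lines, with control values from 3.58 to 201. CG42815 was listed at 0 in control and I172G and mthl8 in I172G. Nuclear ribosomal RNA genes and pseudogenes, 19 in all, held 7.3 ± 1.6% of the normalised counts in control, 8.7 ± 1.6% in I172G, 10.9 ± 1.6% in P223L and 6.3 ± 1.5% in SAMC-null. The mitochondrial ribosomal RNA mt:lrRNA held 3.5 ± 0.1, 3.3 ± 0.2, 5.7 ± 0.5 and 5.3 ± 0.1%.

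Genes changed in I172G lay more often near the carrier gene. Within 3 Mb on either side of CG4743 on 3R, 86 of 659 tested genes (13.1%) were called with a change of at least 2-fold, 26 higher and 60 lower, against 809 of 11258 (7.2%) elsewhere. A hypothesis is a chromosome segment around the edited gene that differs between the I172G line and control, and the values are in line with it: a share of 0.0279 of 10000 circular shifts of the gene order gave as many changed genes in the window. A few clusters of related neighbours, such as the lipase-like genes, would give such an excess too, and the segment cannot be told apart from them here. In I172G 39 of 60 bins of 100 kb held a changed gene, with a median of 27 over the shifts and a share of 0.002 as high. That test decides nothing, because it was also low in P223L, SAMC-null and I172G against P223L (0.0011, 0.0078 and 0.0019), where the share of shifts with as many changed genes was 0.1355, 0.0827 and 0.4087. Between P223L and SAMC-null neither was low (0.3252 for the bins and 0.4629 for the genes). No genotypes of neighbouring sites were used here, so the segment stays a hypothesis.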
